A study of Gallus gallus with 9 samples.

How the data were processed

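Total RNA of chicken thymus was extracted with Trizol and made into Illumina TruSeq libraries, per the labels' protocols, from 3 groups of 3 samples (CON, LPS and GEN). Per the submitters' processing notes, the tools included CASAVA 1.8 and featureCounts 1.5.0-p3, and the genome build was GRCg6a. The aligner, the annotation release, the strand setting and the stage of base calling or filtering at which each tool was used are not given in the sources used here. The deposited table holds FPKM values for 9 libraries, with the chromosome, strand, start, end and length of each gene per the file headers. The table has 0 columns of samples outside the series. Each column is named for one sample's group and replicate number in the labels.

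FPKM values are not counts, so no count model was the main test. In every library the deposited FPKM multiplied by the gene length fell on whole multiples of one step, and 100% of values above 0 came out whole within 0.01. Whole fragments per gene and the total the authors scaled by were recovered from these steps. That total was 1.01 to 1.09 times the sum of fragments in 8 libraries and 0.767 times in CON 3, for a reason not given in the sources used here. One scaling factor per library changes no rank of genes within it.

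Genes with at least 1 FPKM in at least 3 libraries were tested, 13506 of 25016. A limma model with a mean-dependent prior variance was fitted to log2(FPKM + 1), with a pseudocount of 1, to the 9 libraries in one fit, and the 3 contrasts were taken from it. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. An exact two-sided test of single values, 3 against 3, cannot go below 0.1. The design, its tests and most alternatives were fixed before the data were examined, for counts or for normalized values. The table turned out to hold FPKM, so the test planned for normalized values was used and the alternatives planned for counts were not run.

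Gene names could not be used. The reference table at hand, of the GRCg7b assembly, pairs 0 of the 25016 identifiers with a symbol, so the 27 gene lists fixed beforehand (734 symbols for thymocyte, immune, stromal and metabolic functions) and the cell type markers could not be tested. The planned rule for named genes took genes with a symbol and therefore named none. In its place a rule chosen after the data were seen took, in each comparison, the 2 genes higher and the 2 lower with the lowest p among genes with a mean of at least 1 FPKM over the 6 libraries compared, non-overlapping groups and at least 10 recovered fragments in at least 3 libraries. Genes were instead grouped by chromosome, also after the data were seen, and 44 groups with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01.

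Libraries were compared before averaging. No 2 libraries held identical values. A chi-square of the recovered fragments per degree of freedom, over genes with at least 20 fragments in a pair, was 14.9 to 280 between libraries of one group. Libraries thus differed by more than counting error, so none was merely another sequenced again. This cannot tell whether 2 libraries were made from the same RNA. The replicate numbers were checked for pairing and were not used. Depth was 19618047 to 25863282 gene fragments per library, and intervals on shares cover counting error only.

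The test was tried on simulated data drawn from the real genes' means and depths with 200 genes changed in LPS vs CON. The changed genes were picked only among genes with a mean well above the filter of 1 FPKM. The shares recovered thus say nothing of genes near that filter. With all 9 libraries alike, 13577 genes were tested, 76% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold were recovered, and 9 unchanged genes were called. With deviations of the size seen in CON 3 given to 1 CON library, 13559 genes were tested, 19% of the 2-fold and 77% of the 4-fold changes were recovered, and 1 unchanged gene was called. The recovered fragments equalled the simulated ones in 100% of values. For comparisons that share libraries, 20 simulations without effects, with each group's own spread per gene, gave the values expected from the sharing, and 20 simulated sets of libraries, fitted like the data, the numbers of genes under 0.05 in both.

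Alternatives planned beforehand were quantile normalization, limma without the trend, no filter, at least 1 FPKM in at least 6 libraries, a pseudocount of 0.1, only the 6 libraries compared, a replicate block, a fold change of at least 2, an adjusted p under 0.1, and leaving out each library. Those chosen after the data were seen were library quality weights, limma-voom on the recovered fragments with and without such weights, at least 10 fragments in at least 3 libraries, and scaling by the sum of recovered fragments.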

Results

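RNA was sequenced from the thymus, the organ in which T cells mature, of broiler chicks aged 21 days. In all, 3 groups of 3 libraries were compared. The CON chicks received the basic diet. The LPS chicks were treated with lipopolysaccharide, the outer-membrane component of Gram-negative bacteria that provokes an innate immune response. The GEN chicks received lipopolysaccharide together with genistein, an isoflavone of soy that binds oestrogen receptors. The labels give no animal identity beyond the replicate number and no doses, so p-values measure the spread between these samples, which may in part be technical. Expression was available as FPKM (fragments scaled to gene length and to library size) for 25016 genes, of which 24356 carry Ensembl identifiers and 660 are genes predicted by the submitters. Whole fragments could be recovered from the values, and each library held between 19618047 and 25863282 gene fragments. The tests covered 13506 genes with at least 1 FPKM in at least 3 libraries. The files pair no identifier with a gene name, so genes are given by identifier and by position in GRCg6a, the chicken genome build of the submitters' notes.

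CON 3 stood apart from the other 8 libraries. Its correlation with each of them on the log2(FPKM + 1) scale, across genes, was 0.877 to 0.888, while the pairs among the other 8 gave 0.957 to 0.984. The first principal component held 58.9% of the variance and separated CON 3 from the rest. Mitochondrial genes took 3.94% of the gene fragments of CON 3 (95% Wilson interval 3.94% to 3.95%, counting error only) and 1.43% to 1.93% in the other libraries. The 50 most abundant genes took 24.2% of its fragments, against 14.6% to 15.5% elsewhere. Its depth of 20469730 fragments was within the range of the others. Relative to the mean of the other 8 libraries, genes of 300 to 1000 bases were higher in CON 3 than genes over 4000 bases, by a median of 0.87 on the log2 scale. In the other libraries this difference lay between -0.08 and 0.07. The median standard error of a log2 fold change was 0.23 with all 9 libraries, and without CON 3 it was 0.15 in LPS vs CON and in GEN vs CON and 0.14 in GEN vs LPS.

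**Figure D1:**
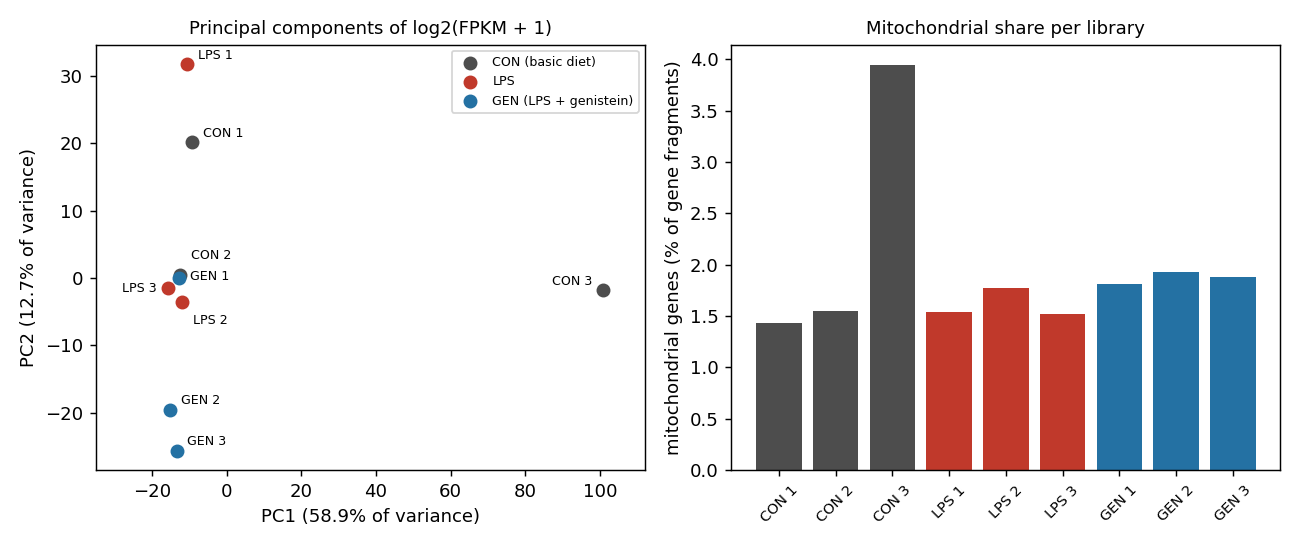
Left, the first 2 principal components of log2(FPKM + 1) over 13506 genes, one dot per library, with 58.9% and 12.7% of the variance on the axes; CON 3 lies alone on the first. Right, the share of gene fragments (in percent) from mitochondrial genes in each library, which is 3.94% in CON 3 and at most 1.93% in the others.

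The comparison of LPS with CON asks which thymic transcripts differed after lipopolysaccharide. The gene with the lowest p among those higher in LPS lies on chromosome 20 (5170329 to 5171174) and was predicted by the submitters. It measured 46.5 ± 8.95 FPKM in LPS and 8.07 ± 6.09 in CON (SD, n = 3 each), a ratio of means of 5.76, and 8.45 ± 1.84 FPKM in GEN. ENSGALG00000019553 on chromosome 2 (67656284 to 67662678) measured 7.85 ± 2.96 FPKM in LPS, 0.867 ± 0.823 in CON and 1.65 ± 0.728 in GEN. Of the genes lower in LPS, ENSGALG00000010986 on chromosome 3 (38100145 to 38113286) measured 2.23 ± 0.745 FPKM against 6.09 ± 1.29 in CON, and 4.71 ± 0.620 in GEN. ENSGALG00000011646 on chromosome 5 (51984130 to 51996689) measured 22.8 ± 1.77 FPKM against 34.3 ± 2.03 in CON, and 28.9 ± 1.41 in GEN.

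None of the 4 passed the test across all genes. Their log2 fold changes on the log2(FPKM + 1) scale were 2.57 (SE 0.40), 2.27 (SE 0.38), -1.15 (SE 0.23) and -0.57 (SE 0.11), each with a limma adjusted p of 0.637. Leaving out CON 2 gave the predicted gene an adjusted p of 0.0246, and over all settings tried its adjusted p ranged from 0.0246 to 0.807. In LPS vs CON as a whole, limma called 0 of 13506 genes at an adjusted p under 0.05, and 611 genes had an unadjusted p under 0.05, where an even spread of p-values gives 675. Of these 611, 331 were higher and 280 lower in LPS, but the direction hung on the scaling and on CON 3: it was 522 higher and 105 lower with libraries scaled by the sum of fragments, 225 higher and 337 lower with quantile normalization, and 360 higher and 426 lower (786) without CON 3. More were lower also without CON 1 (656 higher, 659 lower), with library quality weights (827 and 887) and with these weights in voom (583 and 660). limma-voom on the recovered fragments also called 0 genes, with 550 at an unadjusted p under 0.05. The groups did not overlap for 1652 genes (739 higher, 913 lower), 12.2% of those tested, where chance gives 10% on average for 3 against 3. Genes vary together, so a single split can lie far from 10%, and this share was not set beside other splits. A difference of 1.4-fold was the median half-width of the 95% interval of a gene. The unadjusted count was 1315 without CON 1, 1568 without CON 2, 370 without LPS 2, 340 without LPS 3 and 325 with only the 6 libraries compared in the fit.

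**Figure D2:**
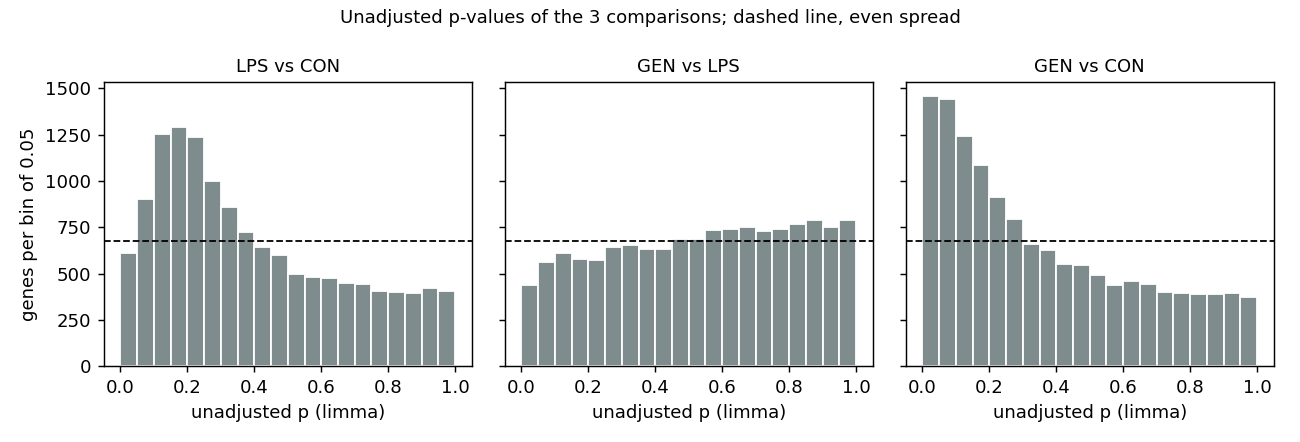
Numbers of genes (vertical axis) per bin of 0.05 of the unadjusted limma p (horizontal axis) in the 3 comparisons, over 13506 genes each; the dashed line marks an even spread, 675 genes per bin. The lowest bin holds 611 genes in LPS vs CON, 438 in GEN vs LPS and 1459 in GEN vs CON.

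The comparison of GEN with LPS asks what genistein changed in lipopolysaccharide-treated chicks. Of the genes lower in GEN, the lowest p belonged to ENSGALG00000047285 on chromosome 3 (107443030 to 107444685). It measured 0.279 ± 0.176 FPKM in GEN (1 to 6 fragments per library), 5.73 ± 2.32 in LPS (49 to 122 fragments) and 0.781 ± 0.665 in CON. A longer gene model on the other strand (107430692 to 107459717) covers its position, and since no strand setting is given, fragments of the 2 cannot be told apart with certainty. The predicted gene on chromosome 20 followed, with 8.45 ± 1.84 FPKM in GEN and 46.5 ± 8.95 in LPS. Of the genes higher in GEN, ENSGALG00000047199 on chromosome 6 (17399196 to 17404437) measured 1.83 ± 0.140 FPKM against 0.561 ± 0.220 in LPS and 0.810 ± 0.276 in CON. ENSGALG00000040355 on chromosome 2 (115280942 to 115286441) measured 5.70 ± 2.04 FPKM against 1.70 ± 0.395 in LPS and 2.55 ± 0.757 in CON.

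These genes did not pass either. In the order given, their log2 fold changes were -2.34 (SE 0.34), -2.33 (SE 0.40), 0.87 (SE 0.18) and 1.27 (SE 0.27), each with a limma adjusted p of 1.0. limma called 0 genes in GEN vs LPS, with 438 at an unadjusted p under 0.05 (235 higher, 203 lower), fewer than the 675 of an even spread. limma-voom called 0, with 484 at an unadjusted p under 0.05. The groups did not overlap for 2731 genes, 20.2%, against 10% on average by chance, and 1204 of these were higher and 1527 lower in GEN. This share was not set beside other splits of the libraries either. CON 3 enters this comparison only through the shared estimate of the spread. Without it, 0 genes were called and 1849 had an unadjusted p under 0.05, and the direction turned, with 853 higher and 996 lower. With only the 6 libraries of GEN and LPS this count was 1703 (775 higher, 928 lower), with quality weights 1815 (866 and 949) and with these weights in voom 1814 (894 and 920). It was 215 without LPS 1 (111 and 104) and 235 without GEN 3 (117 and 118).

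The comparison of GEN with CON asks how chicks given both treatments differed from chicks on the basic diet. It held the lowest p-values of the 3 comparisons. ENSGALG00000009651 on chromosome 9 (22606347 to 22610846) measured 7.83 ± 0.988 FPKM in GEN and 1.55 ± 0.394 in CON, a ratio of 5.04, with LPS between them at 3.96 ± 0.644. ENSGALG00000007998 on chromosome 1 (14925155 to 14945434) measured 13.5 ± 2.59 FPKM in GEN and 3.46 ± 0.588 in CON, a ratio of 3.9, again with LPS between them at 7.07 ± 1.03. Of the genes lower in GEN, ENSGALG00000012218 on chromosome 1 (50847151 to 50849565) measured 10.8 ± 1.03 FPKM against 22 ± 2.96 in CON, with LPS at 13.9 ± 1.81. ENSGALG00000012550 on the same chromosome (52103308 to 52109433) measured 33.6 ± 2.68 FPKM against 53.5 ± 1.79 in CON, with LPS at 44.7 ± 4.84. All 4 kept the order of CON, LPS and GEN in every library. The rule picked genes whose CON and GEN groups do not overlap, so that part of the order was fixed by it. ENSGALG00000009651 lies within the span of a gene model on the other strand, and ENSGALG00000012550 within one on its own strand, so their fragments may not be separate from those neighbours.

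**Figure D3:**
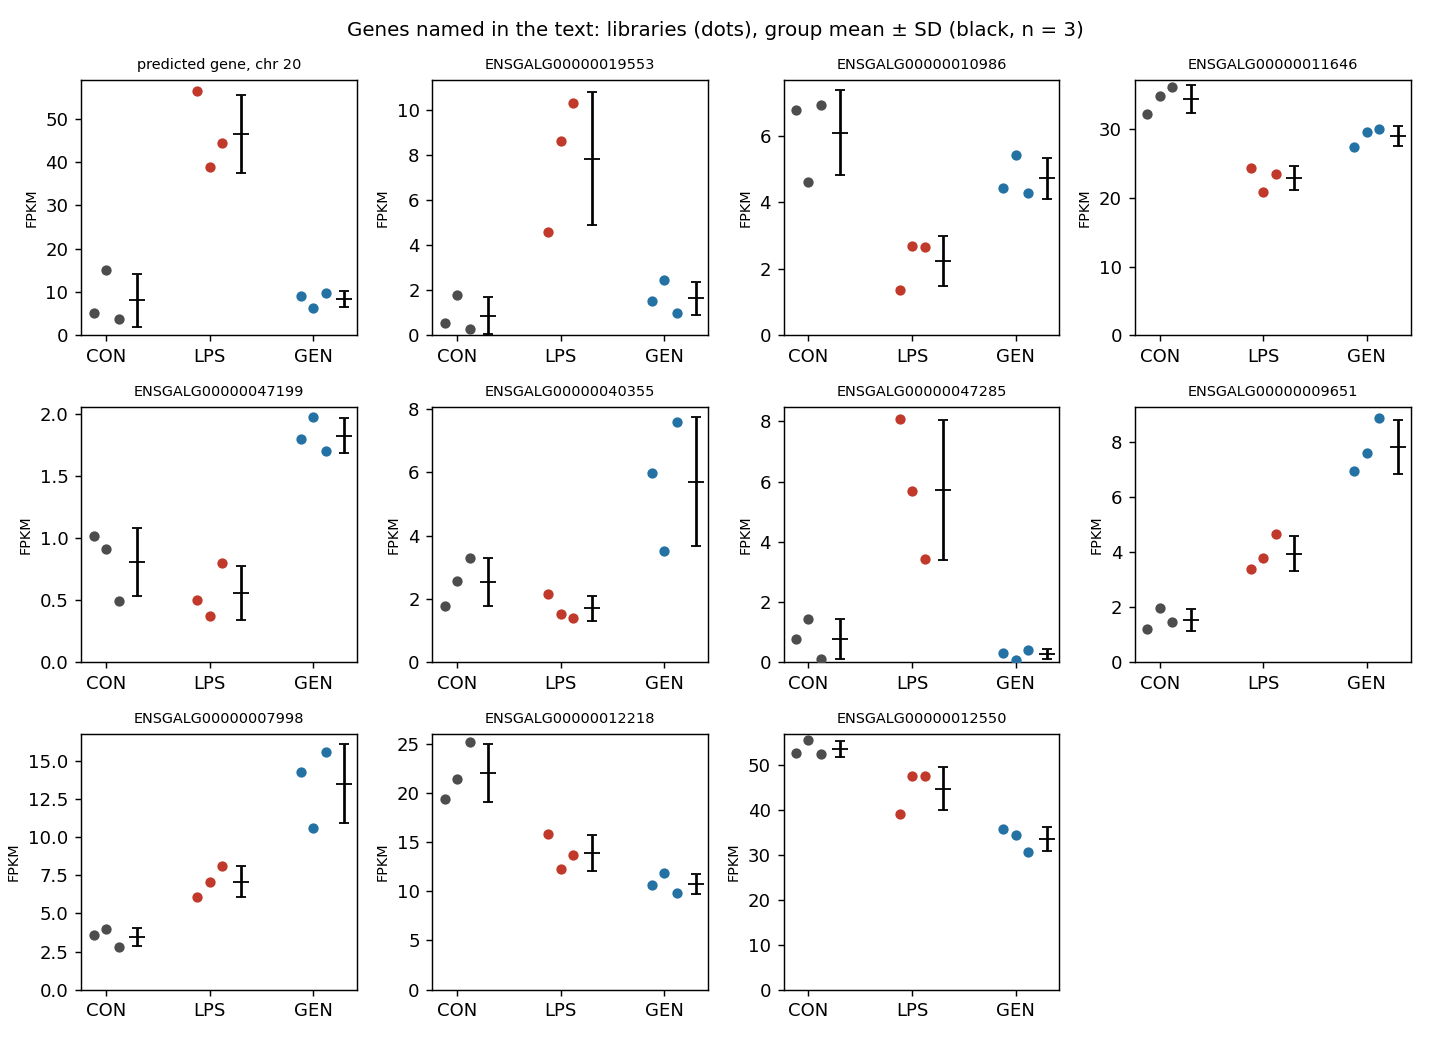
FPKM (vertical axis, linear from 0) of the genes named here in CON, LPS and GEN; dots are libraries and black bars the group mean ± SD (n = 3). The predicted gene on chromosome 20 lies between 38.8 and 56.3 FPKM in LPS and between 3.88 and 15.1 in the other libraries, while ENSGALG00000009651 and ENSGALG00000007998 lie lowest in CON and highest in GEN.

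The first 2 had log2 fold changes of 1.8 (SE 0.18) and 1.69 (SE 0.19) and a limma adjusted p of 0.0629 each. The other 2 had -0.96 (SE 0.15) with an adjusted p of 0.269 and -0.66 (SE 0.12) with an adjusted p of 0.438. limma called 0 genes in GEN vs CON at an adjusted p under 0.05, and 1459 genes had an unadjusted p under 0.05, against 675 for an even spread. Of these, 632 were higher and 827 lower in GEN, while scaling by the sum of fragments gave 1135 higher and 329 lower, and quantile normalization 564 and 799. limma-voom called 0, with 1333 at an unadjusted p under 0.05. The groups did not overlap for 2852 genes, 21.1%, against 10% on average by chance, a share that was not set beside other splits. When each library was weighted by its estimated quality, a setting chosen after the data were seen that gave CON 3 a weight of 0.049, limma called 54 genes, 38 higher and 16 lower in GEN. The 4 genes named above were among these, with adjusted p of 0.0122, 0.0122, 0.0306 and 0.0323, and over all settings tried the adjusted p ranged from 0.0122 to 0.518 for the first 2 and from 0.0306 to 0.7 for the others. Other groupings of the same 6 libraries, against their labels, gave up to 532 calls under this weighting. Leaving CON 3 out altogether called 0 genes, and the limma adjusted p of the 4 named genes was then 0.119, 0.119, 0.163 and 0.163. Without CON 3, 2152 genes had an unadjusted p under 0.05, 888 higher and 1264 lower in GEN. The unadjusted count was 2681 without CON 2, 760 without GEN 2, 678 without GEN 3 and 819 with only the 6 libraries compared. More of these were higher than lower without GEN 2 (403 and 357), with only the 6 libraries (429 and 390) and without a filter (1009 and 984).

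Whether genistein moved transcripts back towards the level of the basic diet was asked by setting LPS vs CON against GEN vs LPS. limma called 0 genes in both comparisons with opposite signs. Across 13506 genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at r = -0.19 (Spearman -0.14). The LPS libraries belong to both comparisons, and simulated data with no effect gave -0.3 (Spearman -0.29). The covariance was -0.021 against -0.026 in the simulations, which had an SD of 0.0016. The correlation moved with single libraries: r was -0.32 without LPS 2, -0.29 without LPS 3, -0.12 without CON 2 and -0.26 without CON 3, where simulations without CON 3 gave -0.47. At an unadjusted p under 0.05 in both, 36 genes were higher in LPS than in CON and lower in GEN than in LPS, and 22 had the opposite pattern, where simulated libraries with no effect gave 54.8 and 52.4 (SD 5.8 and 9.8) and independent lists 4.98 and 4.87. Without CON 3 these numbers were 90 and 107, against 113 and 111 simulated (SD 9.4 and 11) and 26.5 and 26.9 for independent lists. With all 9 libraries the simulations put 439 and 436 genes under 0.05 in both LPS vs CON and GEN vs CON with the same sign. That is more than the 331 and 280 of LPS vs CON as a whole in the data. The simulated counts for all 9 libraries may thus be too high, and the 36 and 22 genes decide nothing. Without CON 3 neither count exceeded what shared libraries alone gave. The covariance without CON 3 was -0.018, against -0.027 in the simulations (SD 0.0013). In both fits the covariance was less negative than simulated, so it too gave no excess of opposite changes. Genes with every LPS library above every CON and GEN library numbered 191, and genes with every LPS library below them 174. Exchangeable libraries would give 161 of each. The shared LPS libraries were not split, since 3 cannot give 2 parts of at least 2.

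LPS and GEN were also compared for shared differences from CON. limma called 0 genes in both with the same sign. The log2 fold changes correlated at r = 0.79 across genes (Spearman 0.79), where simulated data with shared CON libraries and no effect gave 0.82 (Spearman 0.76). The covariance was 0.13 against 0.12 in the simulations (SD 0.0035). Without CON 3 the correlation was 0.58, with 0.56 simulated, and the covariance 0.047, with 0.034 simulated (SD 0.0018). At an unadjusted p under 0.05 in both, 150 genes were higher and 105 lower than in CON, where simulated libraries with shared CON and no effect gave 439 and 436 (SD 24 and 22) and independent lists 15.5 and 17.1. Without CON 3 these numbers were 156 and 171, against 173 and 171 simulated (SD 14 and 12) and 23.7 and 39.9 for independent lists. With all 9 libraries the simulated numbers exceeded the 331 higher and 280 lower genes of LPS vs CON as a whole. The counts with all 9 libraries could thus not exceed them and decide nothing. Without CON 3 the counts gave no excess over shared CON libraries alone. The covariance lay above the simulated one in both fits, a lean to a shared direction whose cause was not tested. The CON libraries were not split, since 3 cannot give 2 parts of at least 2. For 33 genes every LPS library lay above every CON library and every GEN library above every LPS library, and for 91 genes the order was the reverse. Exchangeable libraries would give 8.04 of each.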

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

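The settings with quality weights, voom, the fragment filter and the fragment-sum scaling were chosen after the data were seen. LPS vs CON stayed at 0 called genes under 22 of 23 settings, GEN vs LPS under 22 of 23 and GEN vs CON under 17 of 23. The setting with a fold change of at least 2 only narrows the main calls, so it could give nothing but 0. Leaving out 1 library gave 0 to 1 genes in LPS vs CON (1 without CON 2), 0 in GEN vs LPS and 0 to 1 in GEN vs CON (1 without LPS 3). Without a filter, 1 gene each was called in GEN vs LPS and GEN vs CON, a gene on chromosome 2 with 3 fragments in each GEN library and 0 elsewhere. In GEN vs CON a pseudocount of 0.1 called 1 gene, of 33 bases and at most 5 fragments, an adjusted p under 0.1 called 3, quality weights 54, and voom with quality weights 5. The gene called without LPS 3 had 33 bases and at most 3 fragments. Genes called in both comparisons stayed at 0 for both pairs under every setting run for them. All 12 log2 fold changes of named genes kept their sign in 262 values, of which 9 newly passed the threshold of their setting. For ENSGALG00000009651 and ENSGALG00000007998 these include the looser threshold of 0.1, at an unchanged limma adjusted p of 0.0629. The named genes were picked for groups that do not overlap, so leaving out or weighting libraries could not turn a sign. Filters, the trend and thresholds leave the fold change as it is. The kept signs thus tell little beyond the settings that rescale the libraries. Scaling by the sum of fragments moved the median log2 fold change of all genes to 0.16 in LPS vs CON and 0.18 in GEN vs CON. The labels do not say what the replicate numbers mean. The same-number libraries' deviations correlated at -0.1 to 0.34, 4 of 9 pairs above 0.1, and 4 of 9 libraries correlated best with their own number. Only CON 3 with LPS 3 lay below 0, and the other pairs gave 0.03 to 0.34, so a shared block is not excluded. The replicate block called 0 genes in each comparison, and in GEN vs LPS 3 chromosome groups against 2 (0 with an estimated correlation). This block raised the lowest limma adjusted p of GEN vs CON from 0.063 to 0.3. Alternatives meant for counts and all 27 gene lists were not run. Depth limits the 238 tested genes with under 10 fragments in at least 7 libraries.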

Other observations

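The tests in this part were chosen after the results were seen, apart from the regroupings for the numbers of genes called and of genes called in both comparisons. Grouped by chromosome, tested with camera at its preset correlation, the 27 mitochondrial genes were lower in LPS than in CON (26 of 27, median -0.66 relative to all genes on the log2 scale, adjusted p = 6.1e-05, but 0.77 with an estimated correlation). They were also lower in GEN than in CON (27 of 27, median -0.71, adjusted p = 5.5e-05, but 0.52 with an estimated correlation). The small chromosomes 25, 28, 30 and 33 were called lower in LPS than in CON at the preset correlation, with adjusted p of 0.0024 to 0.042, and each had 0.77 with an estimated one. GEN vs CON called 9 groups lower and 1 higher, the sex chromosome Z, where 395 of 596 genes were higher (median 0.15, adjusted p = 0.0011). With an estimated correlation each of these 10 had an adjusted p of 0.52. CON 3, whose mitochondrial share was 3.94%, carried most of the mitochondrial difference: without it 14 of the 27 genes were higher in LPS (adjusted p = 0.99), and in GEN vs CON 17 of 27 were lower (median -0.139, adjusted p = 0.98). The mitochondrial share of fragments in GEN went the other way without CON 3. It was 1.81% to 1.93% in GEN, 1.43% in CON 1, 1.55% in CON 2 and 1.52% to 1.78% in LPS. Without CON 3, LPS vs CON held 0 groups against 5, GEN vs LPS 10 (8 lower, 2 higher) against 2, and GEN vs CON 4 (1 lower, 3 higher) against 10. Chromosome Z was among these 4 (373 of 596 genes higher, median 0.0857, adjusted p = 0.019 at the preset correlation, but 0.83 with an estimated one), and with an estimated correlation 0 groups passed without CON 3 in each comparison. Leaving out any other single library gave 3 to 10 groups in LPS vs CON, 0 to 8 in GEN vs LPS (0 without LPS 1 or LPS 3, 8 without GEN 1) and 10 to 14 in GEN vs CON. Under quantile normalization the 4 small chromosomes no longer passed in LPS vs CON, nor the mitochondrial genes in GEN vs CON. The 2 groups of GEN vs LPS fell to 0 under quantile normalization and under scaling by the sum of fragments, and the latter raised the 5 of LPS vs CON to 10 and the 10 of GEN vs CON to 14. With an estimated correlation, no group passed in any comparison, the lowest adjusted p being 0.77 in LPS vs CON, 0.76 in GEN vs LPS and 0.52 in GEN vs CON. Among the 10 splits of the 6 libraries, 10 gave as many groups as the 5 of LPS vs CON (highest other 16), 4 as many as the 2 of GEN vs LPS (highest other 6) and 6 as many as the 10 of GEN vs CON (highest other 13), too few splits for a share under 0.05.

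A run of neighbouring genes on chromosome 3 had the strongest mean t of GEN against LPS, though no gene of it passed (limma adjusted p of 1 each). Over 12960 windows of 8 neighbouring tested genes with at least 10 fragments in 3 libraries, the strongest mean t in GEN vs LPS was -2.72, between 107236167 and 107459717, where 7 of 8 genes were lower in GEN, 4 had an unadjusted p under 0.05 and 1 was higher (log2 fold change 0.0329). The summed FPKM of all 8 genes was 278 ± 66.5 in LPS, 208 ± 12.2 in GEN and 233 ± 24.7 in CON (SD, n = 3). LPS 1 was the highest library (355), and LPS 2 and LPS 3 (244 and 236) lay within the range of CON (208 to 258), but 1 gene, at 136 to 221 FPKM, made up most of this sum. The 4 genes with an unadjusted p under 0.05, picked for it, summed to 72.2, 22.6 and 13.8 FPKM in LPS 1, 2 and 3, 1.61 to 3.86 in GEN and 6.73 to 13.6 in CON. Without LPS 1 the mean t of the 8 genes was -2.23, with 7 lower in GEN and 4 at an unadjusted p under 0.05. The run had been picked with LPS 2 and LPS 3 in it, so this decides nothing, and LPS 1 alone stays open as an explanation. Fragments shared between overlapping gene models stay open, since only 1 of the 4 genes at an unadjusted p under 0.05 overlaps no other model, and the genistein treatment stays open as well. The highest mean t of 8 neighbours was as large in 1 of the 10 splits for GEN vs LPS, the real one (2.72, highest other 2.02), in 8 for LPS vs CON (2.04, highest other 3.24) and in 5 for GEN vs CON (2.36, highest other 3.14).

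In all, 3 technical explanations were set against the distance of CON 3 from the other libraries. GEN 1 and GEN 2 had fewer fragments than CON 3 (20420800 and 19618047 against 20469730), and their mean correlations with the other libraries except CON 3 were 0.977 and 0.974, against 0.883 for CON 3. Without the most abundant 5% of genes that of CON 3 was 0.834 (others 0.957 to 0.97), and after a smooth trend with gene length was removed from every library it was 0.886 (others 0.971 to 0.979). These values argue against a low number of fragments, a few abundant genes or a trend with length as the sole cause. A different state of the tissue or RNA, another part of the organ or a wrong label stay open, since without gene names no cell type markers could be read, and no biological explanation was tested.

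Genes of chromosomes 11 and above were called lower in GEN than in CON at the preset correlation (median -0.096 relative to all genes, adjusted p = 0.0011, but 0.52 with an estimated correlation). CON 3 gave most of the size: its median on these chromosomes relative to chromosomes 1 to 10 was 0.3, and the others lay between -0.078 and 0.064. The 3 GEN libraries (-0.039 ± 0.035) lay below the 5 other libraries of CON and LPS (0.021 ± 0.027), by a small gap between the nearest, -0.0083 against -0.0037. Without CON 3 the median of the group in GEN vs CON was -0.0403 with an adjusted p of 0.13. Since the group had been picked with the other GEN and CON libraries in it, this decides nothing, and CON 3 alone stays open as the cause. After removal of the trend with gene length the median was -0.083 (adjusted p = 0.0031 at the preset correlation, before 0.0011), so that most of the difference with all libraries was left. GC content, in which small chicken chromosomes are rich, was not tested for want of a genome sequence, and the treatments remain open.

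The numbers of genes called or near the threshold were set beside other splits of the libraries, with 10 splits per comparison and so no share under 0.1. A real count of 0 is reached by any split, so these counts decide nothing for the 0 genes called in LPS vs CON, GEN vs LPS and GEN vs CON (10 of 10 splits each, highest other count 1). The number of genes at an unadjusted p under 0.05 was as high in 3 splits for LPS vs CON (611, highest other 891), in 1 for GEN vs LPS (438, highest other 328) and in 1 for GEN vs CON (1459, highest other 891). With quality weights all 10 splits again reached the 0 of LPS vs CON (highest other 9) and of GEN vs LPS (highest other 37), and 3 splits reached the 54 of GEN vs CON. Another split, CON 1, GEN 1 and GEN 3 against CON 2, CON 3 and GEN 2, called 532 genes, which points to a structure of the samples or to the weights themselves, and neither was tested. Without weights no other split called more than 1. Of 100 random splits of the 9 libraries, all 100 necessarily reached the 0 genes called in both comparisons, with opposite or with the same signs (highest other count 1 for each), so nothing is decided there either. The 124 genes ordered CON, LPS, GEN or the reverse without overlap were reached by 2 of 100 splits, the real one and one with 269 that joined CON 3 with GEN 2 and GEN 3. A graded difference from CON over LPS to GEN is therefore a hypothesis that random regrouping of the libraries rarely matched, found and tested on the same data.

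Genes with few fragments were frequent among the lowest p-values. Of the 50 genes with the lowest p, 8 in GEN vs LPS and 7 in GEN vs CON had under 10 fragments in at least 7 libraries, where 0.88 would be expected (two-sided Fisher's exact p = 2.3e-06 and 2.5e-05), and 1 in LPS vs CON (p = 0.59). Of the 238 such genes, 150 are shorter than 100 bases. Genes of the W chromosome, which hens carry and cocks lack, had 76 to 102 fragments per library in all 9 libraries, at most 5e-04% of the total, and 0 of 126 reached the tests. These values argue against an uneven mix of sexes behind the chromosome Z difference of GEN vs CON.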
